A study of Mus musculus with 16 samples.

How the data were processed

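RNA from bone marrow-derived macrophages of C57BL/6 mice, which 1 label spells C56BL/6J, was measured on 16 Affymetrix 3' arrays, 4 for each of untreated cells, IFNg, LPS and both, harvested at 24 h. Per the labels, RNA was isolated with Qiagen RNeasy and labelled with biotin by a 3' in vitro transcription kit, and the authors processed the arrays with Affymetrix Expression Console, for which neither a version nor an algorithm is stated. The deposited table holds 1 intensity per probe set and array, linear, with 64 control probe sets. Checked on the values, each array had been scaled to a mean of 500 after trimming 2% of values from each end, and no log or quantile normalization had been applied. The total signal per array ran from 36279980 to 40343734, the highest value from 39234 to 52705 and the lowest from 0.0505 to 0.194. LPS alone was read as 10 ng/ml, the dose stated for LPS.

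Probe sets were assigned to genes with the platform annotation of 2016. Of the probe sets, 34945 named 1 gene, 932 named several and were left out, and 9160 named none and were fitted apart. A gene with several probe sets was represented by the one with the highest mean over all arrays, which applied to 9009 of 18194 genes. Symbols were checked against a reference gene table of the mouse build GRCm38.p6, where 18032 were found. Values were analysed as log2(intensity + 16), the form planned for a linear table. limma 3.58.1 in R 4.3.3 fitted the 4 group means on all 16 arrays with empirical Bayes variances and no covariate. Tests were two-sided, p were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p below 0.05, with the count of at least 2-fold changes beside it. The 7 contrasts were each stimulus against untreated cells, the 3 comparisons between stimulated groups, and the departure of both from the sum of the single effects on the log2 scale. The groups, contrasts, tests, gene lists, named-gene rule and alternatives were chosen before the data were examined, except where said. Exact permutation tests used all 70 regroupings of 8 arrays. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 made tables and figures.

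The 37 gene lists were 27 of macrophage pathways and 10 of other cell types, all named in the text. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a contrast, and again with an estimated correlation. Members not represented by a probe set of their own alone were not measured. Against untreated cells the text names Nrros, all measured NADPH oxidase members, the 5 highest and 5 lowest called genes whose groups did not overlap, and up to 3 of the most changed called members of each called list; in other contrasts 3 take the place of 5. Of 310 called members picked so, 51 lost their call or reversed in some alternative. Most of these were passed over after their values were seen, others for length, so the named members are steadier than the lists. Some listed genes are not reported here.

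Alternatives were quantile normalization, arrays centred on their medians, a filter on low values, a variance trend with robust fitting, array weights, the mean of a gene's probe sets, every probe set (the next brightest for a named gene), only the groups of a contrast, a replicate block, pseudocounts of 1 and 64, and leaving out each array. Leaving out all arrays numbered 1 was added after the data were seen. The procedure was tested on simulated data with 200 of 18194 genes changed in each of 20 runs. It recovered 77.8% of 2-fold and 96.4% of 4-fold changes with 5.89% false calls, and called the shifted list in 20 runs and other lists in 3. The 3' minus 5' signal of Gapdh was 0.0913, 0.155 and 0.188 higher with IFNg, LPS and both than in untreated cells, and that of Actb differed by -0.0369, -0.0711 and -0.0403. With 70 regroupings the smallest p possible is 0.0286, so 1 of these 6 tests alone could not pass after adjustment. The number of arrays limited the precision.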

Results

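Gene expression was measured in macrophages grown from the bone marrow of C57BL/6 mice, on 16 Affymetrix 3' arrays. The cells were left untreated, or were given interferon gamma (IFNg) at 10 ng/ml, bacterial lipopolysaccharide (LPS) at 10 ng/ml, or both together, and were harvested after 24 h. Each of the 4 groups held 4 arrays, described by the submitters as biological replicates. The values were linear, with a trimmed mean of 500 on every array and a median from 44.1 to 58.8. In every group the array numbered 1 stood apart. Across genes, which are not independent replicates, its correlation with the other arrays of its group ran from 0.961 to 0.979, against 0.980 to 0.985 among the arrays numbered 2 to 4. On average the arrays numbered 1 held less signal of 10 fibroblast and stromal markers (log2 difference -3.38 untreated, -2.24 with IFNg, -1.91 with LPS, -1.14 with both) and of 12 granulocyte markers (-2.68, -2.68, -1.34 and -0.64). Of these, 8 and 5 were lower in array 1 in all 4 groups. In untreated array 1 the NF-kB feedback genes were 1.74 higher, the chemokines 1.33 higher and the antiviral genes 1.12 higher than in the other untreated arrays. Changes are given as limma's log2 fold change ± standard error with n = 4 arrays per group.

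The series title names NRROS, a leucine-rich repeat protein, as a negative regulator of reactive oxygen species. Nrros and the subunits of the phagocyte NADPH oxidase, the enzyme that makes superoxide, were therefore compared first. Nrros mRNA fell with LPS by 0.92 on the log2 scale (± 0.12, adjusted p = 5.04e-05) and with both stimuli by 1.49 (± 0.12, adjusted p = 2.61e-07), to 52.9% and 35.5% of the untreated level. Its mean signal was 5911 in untreated cells, 6060 with IFNg, 3133 with LPS and 2095 with both. All 4 arrays with LPS and all 4 with both lay below all 4 untreated arrays (exact permutation p = 0.0286 each, the smallest that 4 against 4 arrays allow). With IFNg alone Nrros did not pass the test (0.032 ± 0.12, 95% interval -0.22 to 0.29, adjusted p = 0.916). It was lower with both stimuli than with IFNg (-1.52 ± 0.12, adjusted p = 3.58e-07) and than with LPS (-0.57 ± 0.12, adjusted p = 0.00827). It was also lower with LPS than with IFNg (-0.95 ± 0.12, adjusted p = 3.38e-05). The comparison of both with LPS lost its call when only those groups were fitted (adjusted p = 0.0692).

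Of the oxidase subunits, Cybb, the catalytic gp91phox, rose with LPS (0.58 ± 0.091, adjusted p = 0.000299) and with both (0.60 ± 0.091, adjusted p = 0.000133). With IFNg it measured 0.092 ± 0.091 (adjusted p = 0.613). Ncf4, the cytosolic p40phox, fell with IFNg (-0.64 ± 0.13, adjusted p = 0.00315) and rose with LPS (0.68 ± 0.13, adjusted p = 0.00114) and with both (0.40 ± 0.13, adjusted p = 0.0273). Between both stimuli and none Ncf4 differed by -0.00069 in the arrays numbered 1 and by 0.53 in the others. That call was lost after quantile normalization (0.22, adjusted p = 0.224), when only those groups were fitted (adjusted p = 0.0886) and without untreated replicate 2, 3 or 4 or IFNg+LPS replicate 2 (0.33 to 0.38, adjusted p from 0.0662 to 0.0896). Cybc1, the chaperone of gp91phox, rose with IFNg (0.59 ± 0.14), LPS (0.88 ± 0.14) and both (0.93 ± 0.14). Its next brightest probe set gave -0.27, -0.36 and -0.35. The other measured members did not pass the test in any comparison with untreated cells. Their changes with IFNg, LPS and both were -0.093 ± 0.11, 0.22 ± 0.11 and 0.17 ± 0.11 for Cyba, 0.20 ± 0.13, 0.25 ± 0.13 and 0.027 ± 0.13 for Ncf1 and 0.052 ± 0.15, -0.09 ± 0.15 and -0.081 ± 0.15 for Rac1. They were -0.15 ± 0.085, 0.025 ± 0.085 and 0.075 ± 0.085 for Rap1a and 0.14 ± 0.41, 0.88 ± 0.41 and 0.72 ± 0.41 for Rac2.

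Rac2, a GTPase that activates the oxidase, was higher in the array numbered 1 than in the others of its group in all 4 groups. Without the arrays numbered 1 it was called higher with IFNg (0.32, adjusted p = 0.0405), LPS (1.06, adjusted p = 1.93e-05) and both (0.80, adjusted p = 9.49e-05). Leaving out untreated replicate 1 alone gave a call with LPS (1.29, adjusted p = 0.0159) and with both (1.14, adjusted p = 0.0246). So did array weights and a replicate block. The next brightest probe set of Rac2 went the other way, with -0.72 for LPS and -0.80 for both. Ncf1 was called higher with LPS without the arrays numbered 1 (0.36, adjusted p = 0.0167), with array weights (0.33, adjusted p = 0.0252) and with the mean of its probe sets (0.46, adjusted p = 0.0304), and Cyba after centring the arrays on their medians (0.34, adjusted p = 0.0202). As a list, the NADPH oxidase genes rose with LPS. Of the 8 measured, 3 were higher, 0 lower (3 and 0 adjusted over the list alone), at adjusted p = 0.00277. The call held with an estimated correlation (adjusted p = 0.0446) and not after quantile normalization (adjusted p = 0.149). The list also rose with both stimuli. Among 8 measured, 3 were higher, 0 lower (3 and 0 adjusted over the list alone), at adjusted p = 0.0271, adjusted p = 0.107 with an estimated correlation. That call was lost after quantile normalization and with the mean of probe sets (adjusted p = 0.508 and 0.0589). With IFNg the list did not pass. Of 8 measured, 1 was higher, 1 lower (1 and 1 adjusted over the list alone), at adjusted p = 0.827.

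**Figure D1:**
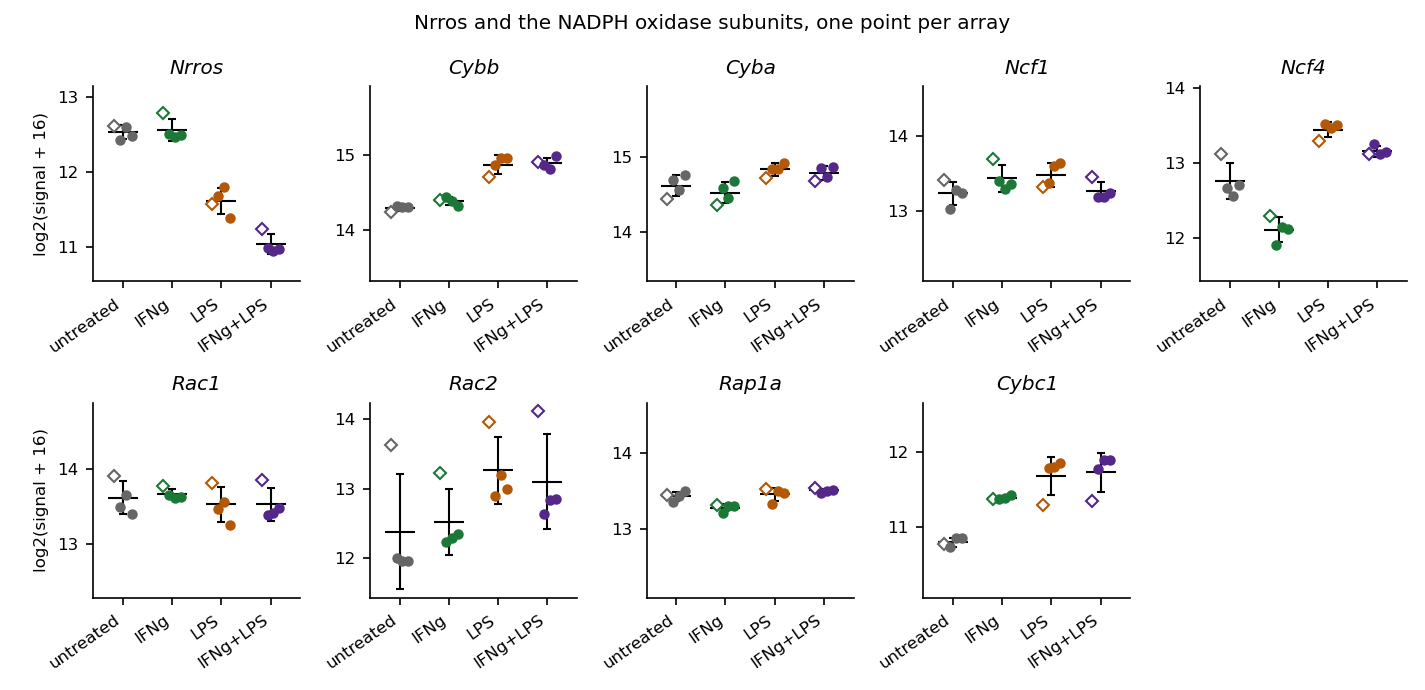
Signal of Nrros and of 8 NADPH oxidase subunits in each of the 16 arrays, as log2(signal + 16), by group. Points are arrays, open diamonds the arrays numbered 1, and bars the mean ± SD of n = 4, and Nrros falls from a mean of 12.53 in untreated cells to 11.61 with LPS and 11.04 with both.

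IFNg alone, the cytokine that T cells and NK cells use to activate macrophages, raised the interferon-inducible GTPases, which act against pathogens inside the cell, and genes of MHC class I presentation. The largest rise was of Cxcl9, a chemokine that attracts activated T cells (10.27 ± 0.31, adjusted p = 1.93e-11), from a mean signal of 3.62 to 24830. It was followed by the guanylate-binding protein Gbp2b (9.45 ± 0.30), by Iigp1 (7.30 ± 0.30), an immunity-related GTPase that acts on vacuoles of pathogens, and by Gbp8 (7.21 ± 0.29) and Gbp6 (6.71 ± 0.32). The largest falls were of Mmp12 (-6.31 ± 0.82), the macrophage elastase, Mamdc2 (-4.94 ± 0.70) and Htr2b (-4.62 ± 0.75), a serotonin receptor. Emp1 (-4.26 ± 0.37), a membrane protein, and Fabp4 (-4.07 ± 0.58), a fatty acid carrier, came next. In untreated replicate 1, Mmp12 (11.26), Mamdc2 (7.20), Htr2b (5.86) and Fabp4 (11.24) lay far below the other untreated arrays on the log2 scale. With a pseudocount of 1 or 64 in place of 16, which also changed the order of other genes, the change of Cxcl9 was 12.40 or 8.49. The next brightest probe set of Emp1 gave -0.76 (adjusted p = 0.215). In all, 2345 of 18194 genes were called, 1120 higher and 1225 lower, and 988 of them changed at least 2-fold. After median centring 1134.0 were higher and 948.0 lower.

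Every measured interferon-inducible GTPase rose. Of the 10 measured, 10 were higher, 0 lower (10 and 0 adjusted over the list alone), at adjusted p = 2.05e-34. The antiviral genes rose, led by Zbp1 (4.23 ± 0.32), a sensor of nucleic acids, Ifit2 (3.76 ± 0.26), which binds viral RNA, and Mx1 (3.30 ± 0.35). Among 23 measured, 20 were higher, 0 lower (21 and 0 adjusted over the list alone), at adjusted p = 1.34e-24, adjusted p = 0.0895 with an estimated correlation. MHC class II presentation rose, with H2-DMa (4.33 ± 0.61), which loads peptides, Ciita (4.14 ± 0.40), the master regulator of the class, and H2-Ab1 (3.66 ± 0.69). Of 11 measured, 10 were higher, 0 lower (10 and 0 adjusted over the list alone), at adjusted p = 5.98e-12, adjusted p = 0.0629 with an estimated correlation. MHC class I presentation rose, with the peptide transporter Tap1 (3.57 ± 0.18), the transactivator Nlrc5 (2.64 ± 0.18) and the immunoproteasome subunit Psmb9 (2.59 ± 0.17). Of the 15 measured, 11 were higher, 0 lower (12 and 0 adjusted over the list alone), at adjusted p = 2.86e-21. Interferon JAK-STAT signalling rose, with the feedback inhibitor Socs1 (5.26 ± 0.27) and the transcription factors Irf1 (3.08 ± 0.14) and Stat2 (1.58 ± 0.24). Among 15 measured, 9 were higher, 1 lower (10 and 2 adjusted over the list alone), at adjusted p = 1.96e-07. Chemokines rose, with Cxcl10 (6.12 ± 0.23) and Ccl8 (5.12 ± 0.48) behind Cxcl9. Of 18 measured, 6 were higher, 1 lower (7 and 3 adjusted over the list alone), at adjusted p = 0.00253, adjusted p = 0.247 with an estimated correlation. Costimulation and checkpoint genes rose, with Cd86 (3.67 ± 0.33) and Cd274 (3.15 ± 0.12), which macrophages show to T cells. Of the 12 measured, 4 were higher, 1 lower (6 and 1 adjusted over the list alone), at adjusted p = 5.7e-05, adjusted p = 0.0629 with an estimated correlation. The inflammasome and cell death list rose, with Mlkl (2.53 ± 0.21), the effector of necroptosis, and Aim2 (1.62 ± 0.36), a DNA sensor. Among 15 measured, 8 were higher, 1 lower (8 and 1 adjusted over the list alone), at adjusted p = 8.31e-07, adjusted p = 0.0895 with an estimated correlation. The calls of the GTPase, MHC class I and JAK-STAT lists held with an estimated correlation.

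Cholesterol synthesis fell with IFNg, led by the enzymes Sqle (-2.28 ± 0.29) and Idi1 (-1.66 ± 0.28). Of 16 measured, 0 were higher, 13 lower (0 and 13 adjusted over the list alone), at adjusted p = 1.83e-10, adjusted p = 0.09 with an estimated correlation. Antioxidant defence fell, with Hmox1 (-1.91 ± 0.33), which breaks down heme, Srxn1 (-1.71 ± 0.38) and thioredoxin reductase Txnrd1 (-1.46 ± 0.35). Of the 19 measured, 1 was higher, 7 lower (2 and 9 adjusted over the list alone), at adjusted p = 0.0109, adjusted p = 0.416 with an estimated correlation. The lysosome list fell, with the protease Ctsk (-2.78 ± 0.42) and the proton pump subunit Atp6v1a (-0.98 ± 0.10) lower and the thioesterase Ppt1 (2.62 ± 0.17) higher. Among 23 measured, 2 were higher, 9 lower (2 and 13 adjusted over the list alone), at adjusted p = 0.000324, adjusted p = 0.287 with an estimated correlation. Oxidative phosphorylation rose, with cytochrome c, Cycs (0.91 ± 0.16), and the complex subunits Ndufs3 (0.80 ± 0.14) and Uqcrfs1 (0.65 ± 0.16). Of 26 measured, 9 were higher, 0 lower (13 and 0 adjusted over the list alone), at adjusted p = 3.41e-06, adjusted p = 0.287 with an estimated correlation. Glycolysis rose, with the hexokinase Hk3 (1.72 ± 0.15) and the phosphofructokinase Pfkp (1.72 ± 0.25). Of the 17 measured, 6 were higher, 0 lower (6 and 0 adjusted over the list alone), at adjusted p = 0.000117, adjusted p = 0.322 with an estimated correlation. The cell cycle list rose, with the mitotic kinase Aurkb (1.44 ± 0.23). Among 27 measured, 7 were higher, 0 lower (8 and 0 adjusted over the list alone), at adjusted p = 5.87e-05, adjusted p = 0.339 with an estimated correlation. Dendritic cell markers rose, with Xcr1 (1.90 ± 0.36), Batf3 (1.37 ± 0.28) and Bst2 (1.30 ± 0.25), of which Bst2 is also an interferon-induced gene. Of 11 measured, 3 were higher, 0 lower (3 and 0 adjusted over the list alone), at adjusted p = 0.0374, adjusted p = 0.155 with an estimated correlation. The dendritic cell call was lost with the mean of each gene's probe sets (adjusted p = 0.117). With the arrays numbered 1 left out, 4214 genes were called. Of the 2345, 2243 (95.7%) kept call and direction. Members higher and lower there were 15 and 0 of 27 for cell cycle, 11 and 1 of 17 for glycolysis, 2 and 11 of 19 for antioxidant defence, 9 and 5 of 18 for chemokines, 15 and 1 of 26 for oxidative phosphorylation, 2 and 15 of 23 for the lysosome and 7 and 1 of 12 for costimulation.

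LPS, the cell wall component that macrophages sense through Tlr4, raised inflammatory cytokines, chemokines and antiviral genes. The largest rises were of Acod1 (8.06 ± 1.16), which makes itaconate, the chemokines Cxcl3 (7.69 ± 0.53) and Cxcl9 (7.68 ± 0.31) and the arginase Arg1 (7.62 ± 0.59). Il1a (7.58 ± 0.85), an inflammatory cytokine, came next, at a mean signal of 34.4 untreated and 14360 with LPS. Its LPS replicate 1 (9.78 on the log2 scale) lay far below the others (13.97 to 14.40). The largest falls were of Hpgd (-6.21 ± 0.24), which degrades prostaglandins, Rasgrp3 (-5.82 ± 0.39), a Ras activator, and Mamdc2 (-5.67 ± 0.70). Ighm (-5.13 ± 0.49), the heavy chain of immunoglobulin M, and Cd28 (-5.05 ± 0.43), a costimulatory receptor best known on T cells, came next. The order changed with the pseudocount, as for Cxcl9 (9.80 with 1 and 5.91 with 64). The next brightest probe set of Hpgd gave -0.86 (adjusted p = 0.056). In all, 4281 of 18194 genes were called, 1594 higher and 2687 lower, and 1834 of them changed at least 2-fold.

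All measured antiviral genes rose with LPS, led by Oasl1 (5.99 ± 0.28) and Mx1 (5.92 ± 0.35). Of the 23 measured, 23 were higher, 0 lower (23 and 0 adjusted over the list alone), at adjusted p = 4.19e-36. Every GTPase rose as well, led by Gbp6 (6.31 ± 0.32) and Iigp1 (5.44 ± 0.30). Among 10 measured, 10 were higher, 0 lower (10 and 0 adjusted over the list alone), at adjusted p = 1.25e-19. Inflammatory cytokines rose, with Il1rn (5.96 ± 0.21), the receptor antagonist, and Il1b (5.93 ± 0.61) behind Il1a. Of 18 measured, 10 were higher, 0 lower (12 and 0 adjusted over the list alone), at adjusted p = 3.09e-09. Chemokines rose, with the monocyte attractant Ccl12 (6.95 ± 0.93) behind Cxcl3 and Cxcl9. Of the 18 measured, 12 were higher, 0 lower (12 and 0 adjusted over the list alone), at adjusted p = 1.84e-15. Nitric oxide, arginine, itaconate and prostaglandin synthesis rose, with prostaglandin E synthase, Ptges (6.08 ± 0.25), behind Acod1 and Arg1. Among 13 measured, 9 were higher, 0 lower (9 and 0 adjusted over the list alone), at adjusted p = 6.93e-09. MHC class I presentation rose, with Nlrc5 (2.20 ± 0.18) and Psmb9 (2.00 ± 0.17). Of 15 measured, 9 were higher, 0 lower (10 and 0 adjusted over the list alone), at adjusted p = 1e-13. JAK-STAT genes rose, with the transcription factor Stat2 (2.68 ± 0.24) and the kinase Jak2 (2.46 ± 0.10). Of the 15 measured, 8 were higher, 2 lower (9 and 4 adjusted over the list alone), at adjusted p = 0.000138. These 7 lists and the NADPH oxidase kept their call with an estimated correlation.

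The NF-kB feedback genes, which limit Toll-like receptor signals, rose, with Traf1 (4.02 ± 0.47) and Irak3 (2.82 ± 0.49), and were higher in untreated array 1 than in the other untreated arrays. Among 16 measured, 12 were higher, 0 lower (13 and 0 adjusted over the list alone), at adjusted p = 7.49e-10, adjusted p = 0.172 with an estimated correlation. Pattern recognition rose, with the scavenger receptors Marco (5.78 ± 1.24) and Msr1 (2.87 ± 0.26). Of 20 measured, 8 were higher, 3 lower (10 and 3 adjusted over the list alone), at adjusted p = 0.000559, adjusted p = 0.127 with an estimated correlation. Glycolysis rose, with its activator Pfkfb3 (3.15 ± 0.16) and the glucose transporter Slc2a1 (1.63 ± 0.32) higher and the aldolase Aldoc (-2.17 ± 0.45) lower. Of the 17 measured, 12 were higher, 1 lower (13 and 3 adjusted over the list alone), at adjusted p = 2.13e-06, adjusted p = 0.182 with an estimated correlation. Costimulation rose, with Cd274 (3.86 ± 0.12) and Cd86 (3.68 ± 0.33). Among 12 measured, 6 were higher, 2 lower (7 and 4 adjusted over the list alone), at adjusted p = 0.00277, adjusted p = 0.114 with an estimated correlation. The inflammasome and cell death list rose, with Zbp1 (4.77 ± 0.32) and Mlkl (3.53 ± 0.21) and Casp4 (2.22 ± 0.24), a sensor of intracellular LPS. Of 15 measured, 9 were higher, 2 lower (9 and 2 adjusted over the list alone), at adjusted p = 3.24e-05, adjusted p = 0.114 with an estimated correlation. Cell cycle genes fell, led by Rrm2 (-3.29 ± 0.32), which makes deoxynucleotides, and Birc5 (-2.63 ± 0.38) and Cdc20 (-2.40 ± 0.39) of mitosis. Of the 27 measured, 0 were higher, 21 lower (1 and 22 adjusted over the list alone), at adjusted p = 1.43e-10, adjusted p = 0.114 with an estimated correlation. Cholesterol synthesis fell, led by Sqle (-2.89 ± 0.29) and Idi1 (-2.70 ± 0.28). Among 16 measured, 0 were higher, 13 lower (0 and 15 adjusted over the list alone), at adjusted p = 1.33e-11, adjusted p = 0.0604 with an estimated correlation. Ribosomal proteins fell with LPS. Of 11 measured, 0 were higher, 5 lower (0 and 5 adjusted over the list alone), at adjusted p = 0.0121, adjusted p = 0.442 with an estimated correlation. The ribosomal call was lost after centring arrays on their medians and without the arrays numbered 1 (adjusted p = 0.15 and 0.0515). MHC class II presentation did not pass with LPS. Of the 11 measured, 1 was higher, 1 lower (0 and 0 adjusted over the list alone), at adjusted p = 0.854. Nor did antioxidant defence. Among 19 measured, 7 were higher, 4 lower (7 and 4 adjusted over the list alone), at adjusted p = 0.223. Centring arrays on their medians moved the median change of all genes from -0.075 to 0.052 and the share of called genes that were lower from 62.8% to 48.7%. With the arrays numbered 1 left out 5839 genes were called. Of the 4281, 4015 (93.8%) kept call and direction. There the members higher and lower were 5 and 0 of 8 for the NADPH oxidase.

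Both stimuli together, the classical activation of macrophages, raised interferon-inducible GTPases along with inflammatory cytokines and chemokines. The largest rises were of Cxcl9 (10.70 ± 0.31) at a mean signal of 32750, of Clic5 (8.57 ± 0.49), a chloride channel protein, and of Acod1 (8.09 ± 1.16), Gbp6 (7.40 ± 0.32) and Iigp1 (7.40 ± 0.30). The largest falls were of Igfbp4 (-6.45 ± 0.34), which binds insulin-like growth factors, and of Hpgd (-6.32 ± 0.24), Rasgrp3 (-5.99 ± 0.39), Ighm (-5.97 ± 0.49) and Mamdc2 (-5.71 ± 0.70). The inducible nitric oxide synthase Nos2 (6.89 ± 0.27) reached a mean signal of 2744, against 3.11 with IFNg and 292 with LPS. In all, 5761 of 18194 genes were called, 2123 higher and 3638 lower, and 2602 of them changed at least 2-fold.

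Nitric oxide, arginine, itaconate and prostaglandin synthesis rose with both stimuli, with cyclooxygenase, Ptgs2 (7.14 ± 0.54), beside Acod1 and Nos2. Of 13 measured, 11 were higher, 0 lower (11 and 0 adjusted over the list alone), at adjusted p = 9.08e-09. Inflammatory cytokines rose, with Il1a (6.21 ± 0.85) and Il1rn (6.13 ± 0.21). Of the 18 measured, 9 were higher, 0 lower (11 and 0 adjusted over the list alone), at adjusted p = 4.16e-07. Chemokines rose, with Cxcl10 (7.39 ± 0.23) and Cxcl11 (7.36 ± 0.53) behind Cxcl9. Among 18 measured, 12 were higher, 0 lower (12 and 0 adjusted over the list alone), at adjusted p = 2.76e-11. All measured GTPases rose. Of 10 measured, 10 were higher, 0 lower (10 and 0 adjusted over the list alone), at adjusted p = 4.57e-20. MHC class I presentation rose, with Tap1 (3.95 ± 0.18) and Nlrc5 (3.43 ± 0.18). Of the 15 measured, 11 were higher, 0 lower (12 and 0 adjusted over the list alone), at adjusted p = 1.58e-12. JAK-STAT genes rose, with Socs1 (6.41 ± 0.27) and Irf1 (3.43 ± 0.14). Among 15 measured, 11 were higher, 1 lower (12 and 1 adjusted over the list alone), at adjusted p = 2.39e-06. These 6 lists kept their call with an estimated correlation. Antiviral genes rose, with Oasl1 (6.26 ± 0.28) and Mx1 (6.08 ± 0.35). Of 23 measured, 23 were higher, 0 lower (23 and 0 adjusted over the list alone), at adjusted p = 1.63e-26, adjusted p = 0.0622 with an estimated correlation. MHC class II presentation rose, with H2-Oa (2.88 ± 0.27), a regulator of peptide loading. Of the 11 measured, 3 were higher, 0 lower (3 and 0 adjusted over the list alone), at adjusted p = 0.00669, adjusted p = 0.401 with an estimated correlation. NF-kB feedback rose, with Socs3 (5.58 ± 0.77) and Traf1 (4.54 ± 0.47). Among 16 measured, 14 were higher, 0 lower (14 and 0 adjusted over the list alone), at adjusted p = 2.43e-09, adjusted p = 0.178 with an estimated correlation. Costimulation rose, with Cd86 (5.92 ± 0.33) and Cd40 (5.87 ± 0.43). Of 12 measured, 7 were higher, 1 lower (7 and 1 adjusted over the list alone), at adjusted p = 9.25e-05, adjusted p = 0.0565 with an estimated correlation. The inflammasome and cell death list rose, with Mlkl (3.93 ± 0.21) and Casp4 (2.89 ± 0.24). Of the 15 measured, 10 were higher, 2 lower (10 and 3 adjusted over the list alone), at adjusted p = 1.33e-05, adjusted p = 0.107 with an estimated correlation. Pattern recognition rose, with Marco (4.73 ± 1.24) and Clec4e (4.65 ± 0.51). Among 20 measured, 9 were higher, 4 lower (9 and 4 adjusted over the list alone), at adjusted p = 0.0212, adjusted p = 0.299 with an estimated correlation.

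Glycolysis rose with both stimuli, with Pfkfb3 (2.88 ± 0.16) and Slc2a1 (2.53 ± 0.32) and the lactate exporter Slc16a3 (2.47 ± 0.42). Of 17 measured, 15 were higher, 1 lower (15 and 2 adjusted over the list alone), at adjusted p = 4.64e-09, adjusted p = 0.107 with an estimated correlation. Antioxidant defence rose, with the cystine transporter Slc7a11 (4.45 ± 0.59), the superoxide dismutase Sod2 (2.61 ± 0.21) and Hmox1 (2.34 ± 0.33). Of the 19 measured, 9 were higher, 3 lower (9 and 3 adjusted over the list alone), at adjusted p = 0.0148, adjusted p = 0.415 with an estimated correlation. The TCA cycle list fell, with Idh1 (-2.74 ± 0.18), a cytosolic isocitrate dehydrogenase, and Suclg2 (-1.96 ± 0.14). Among 19 measured, 3 were higher, 8 lower (3 and 9 adjusted over the list alone), at adjusted p = 0.0405, adjusted p = 0.628 with an estimated correlation. The cell cycle list fell, led by Rrm2 (-4.13 ± 0.32) and Birc5 (-3.99 ± 0.38). Of 27 measured, 1 was higher, 23 lower (1 and 23 adjusted over the list alone), at adjusted p = 7.24e-11, adjusted p = 0.107 with an estimated correlation. Cholesterol synthesis fell, led by Idi1 (-3.79 ± 0.28) and Cyp51 (-2.75 ± 0.22). Of the 16 measured, 0 were higher, 15 lower (0 and 15 adjusted over the list alone), at adjusted p = 7.1e-11, adjusted p = 0.0721 with an estimated correlation. Ribosomal proteins fell, with Rps18 (-1.13 ± 0.14) and Rps19 (-1.10 ± 0.15). Among 11 measured, 0 were higher, 9 lower (0 and 11 adjusted over the list alone), at adjusted p = 2.03e-05, adjusted p = 0.136 with an estimated correlation. Quantile normalization ended the calls of antioxidant defence and pattern recognition (adjusted p = 0.104 and 0.0593). The TCA cycle call was lost without the arrays numbered 1, with the mean of probe sets, after median centring and with a replicate block (adjusted p = 0.283, 0.054, 0.0559 and 0.0574). With the arrays numbered 1 left out 6940 genes were called. Of the 5761, 5359 (93%) kept call and direction. There the members higher and lower were 9 and 1 of 11 for MHC class II.

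**Figure D2:**
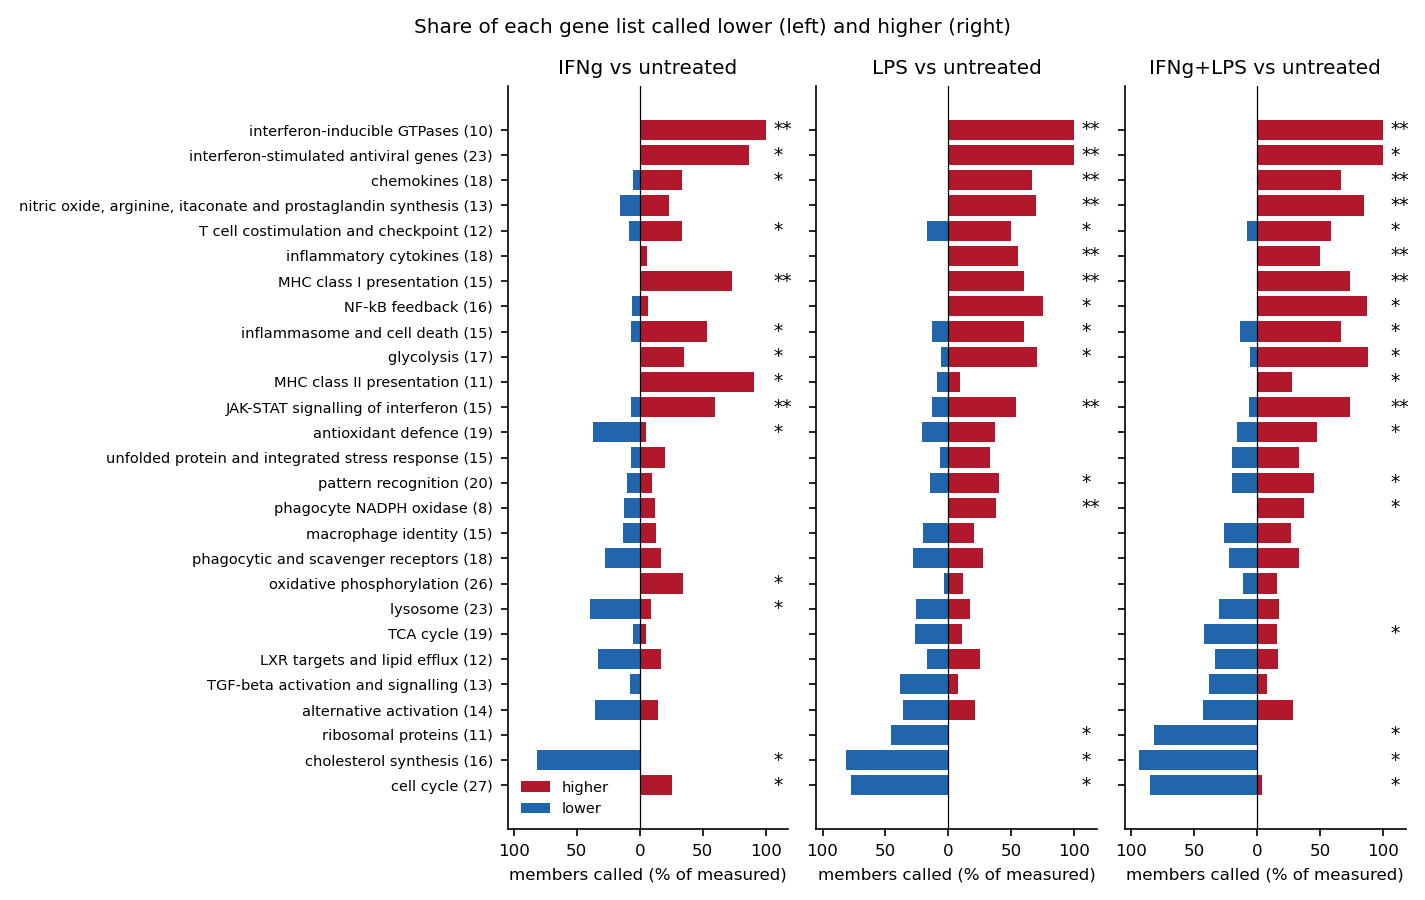
Percent of the measured members of each of the 27 pathway lists called higher (right, red) or lower (left, blue) against untreated cells, with n = 4 arrays per group and the number measured in brackets. One star marks a camera call and a pair of stars a call that also holds with an estimated correlation, and the GTPase list stands at 10 of 10 members higher in all 3 comparisons.

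The remaining pathway lists did not pass in any comparison with untreated cells, and their values follow for IFNg, LPS and both in turn. Macrophage identity held members that went both ways. Of 15 measured, 2, 3 and 4 were higher and 2, 3 and 4 lower, adjusted p = 0.542, 0.424 and 0.762. Phagocytic and scavenger receptors held Marco (4.73 ± 1.24), given here as its change with both stimuli. Of 18 measured, 3, 5 and 6 were higher and 5, 5 and 4 lower, adjusted p = 0.542, 0.77 and 0.702. Alternative activation held the mannose receptor Mrc1 (-5.67 ± 0.18). Of 14 measured, 2, 3 and 4 were higher and 5, 5 and 6 lower, adjusted p = 0.295, 0.851 and 0.847. TGF-beta activation and signalling held the integrin subunit Itgb8 (2.56 ± 0.47). Of 13 measured, 0, 1 and 1 were higher and 1, 5 and 5 lower, adjusted p = 0.827, 0.366 and 0.18. LXR targets and lipid efflux held the apolipoprotein Apoc2 (-2.43 ± 0.29). Of 12 measured, 2, 3 and 2 were higher and 4, 2 and 4 lower, adjusted p = 0.134, 0.909 and 0.367. The unfolded protein and integrated stress response held Trib3 (1.83 ± 0.41). Of 15 measured, 3, 5 and 5 were higher and 1, 1 and 3 lower, adjusted p = 0.398, 0.174 and 0.202. Adjusted over the list alone, the members higher and lower with both were 4 and 4 for macrophage identity, 6 and 4 for the receptors and 4 and 6 for alternative activation. They were 1 and 5 for TGF-beta, 2 and 4 for LXR targets and 5 and 3 for the stress response.

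Among the 10 lists of other cell types only the dendritic cell markers passed, with IFNg. The values of the others follow in the same order. Fibroblast and stromal markers, lower in the arrays numbered 1, did not pass. Of 10 measured, 0, 1 and 0 were higher and 0, 0 and 0 lower, adjusted p = 0.398, 0.824 and 0.592. Of 12 granulocyte markers measured, 1, 1 and 1 were higher and 1, 0 and 2 lower, adjusted p = 0.827, 0.77 and 0.762. T cell markers held Cd28 (-4.84 ± 0.43). Of 10 measured, 0, 1 and 1 were higher and 2, 1 and 2 lower, adjusted p = 0.398, 0.824 and 0.869. B cell markers held Ighm (-5.97 ± 0.49). Of 9 measured, 0, 0 and 1 were higher and 2, 3 and 3 lower, adjusted p = 0.302, 0.42 and 0.24. NK cell markers held the receptor Klrk1 (3.13 ± 0.41). Of 8 measured, 1, 0 and 1 were higher and 0, 0 and 0 lower, adjusted p = 0.172, 0.499 and 0.424. Of 6 megakaryocyte markers measured, 0, 0 and 0 were higher and 1, 0 and 0 lower, adjusted p = 0.133, 0.77 and 0.76. Of 8 mast cell and basophil markers measured, 0, 0 and 1 were higher and 1, 0 and 0 lower, adjusted p = 0.664, 0.499 and 0.509. Of 7 erythroid markers measured, 0, 0 and 1 were higher and 0, 1 and 0 lower, adjusted p = 0.994, 0.762 and 0.659. Of 9 endothelial markers measured, 0, 0 and 0 were higher and 0, 1 and 1 lower, adjusted p = 0.352, 0.762 and 0.898. Adjusted over the list alone, the markers higher and lower with both were 0 and 0 of fibroblasts, 1 and 0 of granulocytes, 3 and 2 of T cells, 1 and 3 of B cells and 1 and 0 of NK cells. No megakaryocyte, mast cell, erythroid or endothelial marker was called so. Without the arrays numbered 1, 5 of 10 fibroblast markers (median -1.91) and 7 of 12 granulocyte markers (median -1.18) were lower with both. The median, the mean and the test differed in sign, always without a call, in these lists. With IFNg they were granulocyte and T cell markers. With LPS they were antioxidant defence, MHC class II, LXR targets, phagocytic receptors, macrophage identity and the granulocyte, dendritic cell, megakaryocyte and fibroblast markers. With both they were oxidative phosphorylation, macrophage identity and the T cell and erythroid markers. For both against IFNg they were GTPases, macrophage identity and the T cell, fibroblast and endothelial markers. For both against LPS they were cytokines, chemokines, alternative activation, the stress response and the megakaryocyte, mast cell and endothelial markers. For LPS against IFNg they were LXR targets, phagocytic receptors, the inflammasome and the granulocyte, T cell, B cell and endothelial markers. For the departure from additivity they were TGF-beta, nitric oxide synthesis, glycolysis and fibroblast markers.

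**Figure D3:**
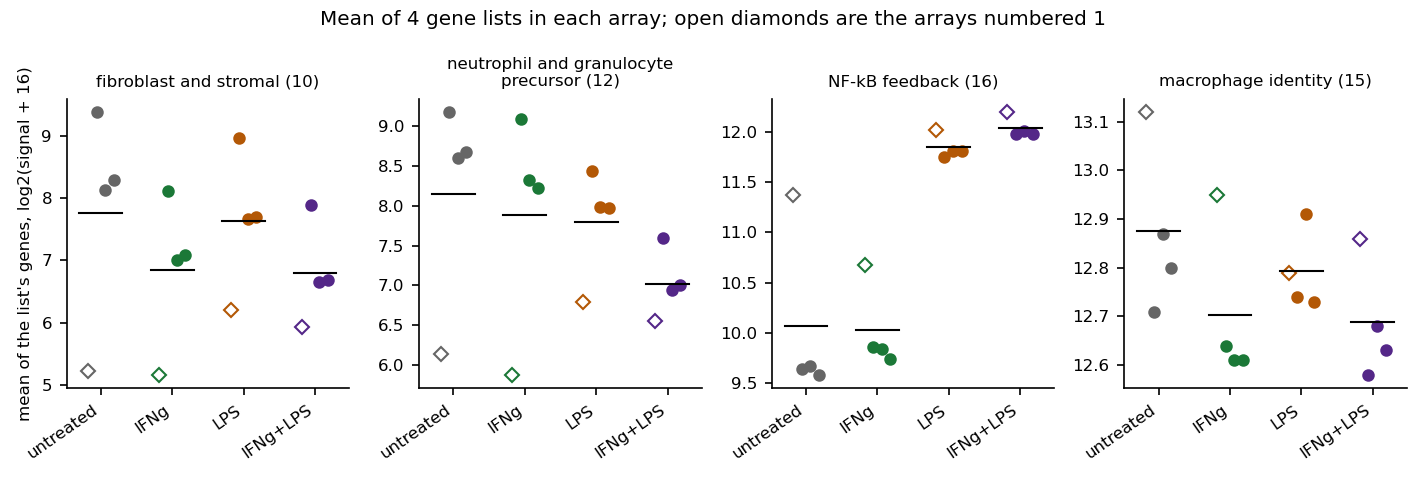
Mean over the members of 4 gene lists in each of the 16 arrays, as log2(signal + 16), by group, with open diamonds for the arrays numbered 1 and lines for the group means. The fibroblast mean of array 1 lies below the other arrays of its group by 3.38 in untreated cells and by 1.14 with both stimuli.

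Genes that IFNg and LPS changed in the same direction were counted. The stimuli raised 442 genes in common and lowered 569 in common, and 257 were called in opposite directions. The 1011 in common became 2064 without the arrays numbered 1, 2012 with array weights and 1618 with every probe set tested. Independent lists of these sizes would share 98.1 and 181 genes. With the untreated arrays split so that each comparison had its own, 269 to 311 genes were higher and 255 to 322 lower in both over 6 splits. Across genes, which are not independent replicates, the changes correlated at 0.398. In 20 simulations without effects shared controls gave 0.503, which is not comparable. The covariances were 0.199 and 0.0424.

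Set against each other, LPS gave more of the neutrophil attractant Cxcl3 (9.05 ± 0.53), of Serpinb2 (8.77 ± 0.73), a protease inhibitor, and of Il1a (8.65 ± 0.85) than IFNg did. It gave less of Gbp2b (-8.53 ± 0.30) and Ighm (-6.64 ± 0.49) and of Rnase6 (-6.48 ± 0.45), an antimicrobial ribonuclease. In all, 4283 of 18194 genes were called, 1815 higher and 2468 lower, and 1833 of them changed at least 2-fold. After median centring 2021.0 were higher and 1937.0 lower. MHC class II presentation was lower with LPS, with Ciita (-5.34 ± 0.40) and H2-DMa (-4.94 ± 0.61). Of 11 measured, 0 were higher, 10 lower (0 and 10 adjusted over the list alone), at adjusted p = 1.15e-07, adjusted p = 0.176 with an estimated correlation. GTPases were lower, with Gbp8 (-5.24 ± 0.29) and Iigp1 (-1.86 ± 0.30) behind Gbp2b. Of the 10 measured, 0 were higher, 9 lower (0 and 9 adjusted over the list alone), at adjusted p = 2.89e-06, adjusted p = 0.199 with an estimated correlation. Antiviral genes were higher, with Isg20 (5.43 ± 0.52) and Oasl1 (3.77 ± 0.28). Among 23 measured, 20 were higher, 0 lower (21 and 0 adjusted over the list alone), at adjusted p = 1.7e-16, adjusted p = 0.199 with an estimated correlation. Cytokines were higher, with Il1b (7.05 ± 0.61) and Il6 (6.24 ± 0.62). Of 18 measured, 6 were higher, 1 lower (8 and 1 adjusted over the list alone), at adjusted p = 2.9e-05, adjusted p = 0.0556 with an estimated correlation. Chemokines were higher, with Cxcl2 (7.81 ± 0.75) behind Cxcl3. Of the 18 measured, 10 were higher, 1 lower (12 and 1 adjusted over the list alone), at adjusted p = 4.96e-07, adjusted p = 0.0815 with an estimated correlation. NF-kB feedback was higher, with Traf1 (4.21 ± 0.47). Among 16 measured, 13 were higher, 0 lower (13 and 0 adjusted over the list alone), at adjusted p = 1.66e-09, adjusted p = 0.267 with an estimated correlation. Nitric oxide, arginine, itaconate and prostaglandin synthesis was higher, with Arg1 (7.13 ± 0.59) and Ptges (6.21 ± 0.25), a call that held with an estimated correlation. Of 13 measured, 7 were higher, 1 lower (9 and 1 adjusted over the list alone), at adjusted p = 9.52e-07. Cell cycle genes were lower, with Rrm2 (-4.50 ± 0.32) and Birc5 (-3.71 ± 0.38). Of the 27 measured, 0 were higher, 21 lower (0 and 23 adjusted over the list alone), at adjusted p = 1.53e-15, adjusted p = 0.118 with an estimated correlation.

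Antioxidant defence was higher with LPS than with IFNg, led by Slc7a11 (5.23 ± 0.59) and Hmox1 (3.88 ± 0.33). Among 19 measured, 8 were higher, 2 lower (8 and 2 adjusted over the list alone), at adjusted p = 0.00331, adjusted p = 0.465 with an estimated correlation. Pattern recognition was higher, led by Clec4e (6.65 ± 0.51) and Marco (6.47 ± 1.24). Of 20 measured, 8 were higher, 3 lower (10 and 3 adjusted over the list alone), at adjusted p = 0.0187, adjusted p = 0.45 with an estimated correlation. The NADPH oxidase was higher, led by Ncf4 (1.32 ± 0.13) and Cybb (0.48 ± 0.091). Of the 8 measured, 3 were higher, 0 lower (3 and 0 adjusted over the list alone), at adjusted p = 0.0115, adjusted p = 0.136 with an estimated correlation. Glycolysis was higher, with Pfkfb3 (1.97 ± 0.16) higher and Pfkp (-2.38 ± 0.25) lower. Among 17 measured, 10 were higher, 4 lower (10 and 4 adjusted over the list alone), at adjusted p = 0.0486, adjusted p = 0.597 with an estimated correlation. The lysosome list was higher, with Ctsk (3.94 ± 0.42) higher and Ppt1 (-2.88 ± 0.17) lower. Of 23 measured, 9 were higher, 5 lower (10 and 5 adjusted over the list alone), at adjusted p = 0.0367, adjusted p = 0.578 with an estimated correlation. The TCA cycle was lower, led by Mdh1 (-1.18 ± 0.19) and Fh1 (-1.08 ± 0.17). Of the 19 measured, 1 was higher, 9 lower (2 and 9 adjusted over the list alone), at adjusted p = 0.0115, adjusted p = 0.578 with an estimated correlation. Oxidative phosphorylation was lower, led by Uqcrfs1 (-0.92 ± 0.16) and Ndufb5 (-0.67 ± 0.15). Among 26 measured, 0 were higher, 10 lower (0 and 11 adjusted over the list alone), at adjusted p = 0.0115, adjusted p = 0.578 with an estimated correlation. Cholesterol synthesis was lower, with Cyp51 (-1.09 ± 0.22). Of 16 measured, 0 were higher, 7 lower (0 and 9 adjusted over the list alone), at adjusted p = 0.00467, adjusted p = 0.575 with an estimated correlation. Ribosomal proteins were lower. Of the 11 measured, 0 were higher, 5 lower (0 and 5 adjusted over the list alone), at adjusted p = 0.0115, adjusted p = 0.534 with an estimated correlation. Quantile normalization ended the calls of glycolysis, the lysosome and the NADPH oxidase (adjusted p = 0.222, 0.209 and 0.0979). Median centring ended those of glycolysis, oxidative phosphorylation and ribosomal proteins (adjusted p = 0.0965, 0.0549 and 0.0683), and the mean of probe sets that of the lysosome (adjusted p = 0.33). A replicate block ended those of glycolysis and the lysosome (adjusted p = 0.0534 each). Leaving out the arrays numbered 1 ended those of the TCA cycle, cholesterol synthesis and the lysosome (adjusted p = 0.0832, 0.0794 and 0.0832). In that fit 5628 genes were called. Of the 4283, 4028 (94%) kept call and direction. Members higher and lower there were 5 and 0 of 8 for the NADPH oxidase.

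LPS added to IFNg raised Il1a (7.28 ± 0.85), Cxcl3 (7.23 ± 0.53) and Nos2 (7.06 ± 0.27), an order that changed with the pseudocount. With a pseudocount of 64, Cxcl2 (6.37), Il1b (6.28) and Clec4e (6.15) stood above Cxcl3 (5.65), Il1a (5.62) and Nos2 (5.28). It lowered Ighm (-7.48 ± 0.49), Myh10 (-6.21 ± 0.27), a non-muscle myosin whose next brightest probe set gave 0.27, and Rrm2 (-5.34 ± 0.32). In all, 4970 of 18194 genes were called, 1989 higher and 2981 lower, and 2118 of them changed at least 2-fold. Nitric oxide, arginine, itaconate and prostaglandin synthesis rose, with Ptges (5.20 ± 0.25) and Slc7a2 (5.03 ± 0.74), a call that held with an estimated correlation. Among 13 measured, 9 were higher, 0 lower (10 and 0 adjusted over the list alone), at adjusted p = 2.15e-08. Cytokines rose, with Il1b (6.67 ± 0.61) and Il6 (6.47 ± 0.62). Of 18 measured, 8 were higher, 0 lower (8 and 0 adjusted over the list alone), at adjusted p = 7.83e-05, adjusted p = 0.0673 with an estimated correlation. Chemokines rose, with Cxcl2 (7.06 ± 0.75) and Ccl7 (5.22 ± 0.82). Of the 18 measured, 9 were higher, 0 lower (10 and 0 adjusted over the list alone), at adjusted p = 1.89e-07, adjusted p = 0.0673 with an estimated correlation. NF-kB feedback rose, with Traf1 (4.74 ± 0.47) and Nfkbie (2.85 ± 0.38). Among 16 measured, 14 were higher, 0 lower (14 and 0 adjusted over the list alone), at adjusted p = 2.58e-10, adjusted p = 0.294 with an estimated correlation. Antiviral genes rose, with Isg20 (4.35 ± 0.52) and Oasl1 (4.04 ± 0.28). Of 23 measured, 21 were higher, 0 lower (21 and 0 adjusted over the list alone), at adjusted p = 8.14e-13, adjusted p = 0.308 with an estimated correlation. Antioxidant defence rose, with Slc7a11 (5.49 ± 0.59) and Hmox1 (4.25 ± 0.33) and glutathione reductase, Gsr (3.08 ± 0.21). Of the 19 measured, 10 were higher, 1 lower (11 and 1 adjusted over the list alone), at adjusted p = 8.45e-05, adjusted p = 0.308 with an estimated correlation. Glycolysis rose, with Slc16a3 (2.53 ± 0.42) and Slc2a1 (2.17 ± 0.32). Among 17 measured, 12 were higher, 2 lower (12 and 2 adjusted over the list alone), at adjusted p = 7.83e-05, adjusted p = 0.391 with an estimated correlation. Costimulation rose, with Cd40 (3.18 ± 0.43) and Cd86 (2.25 ± 0.33). Of 12 measured, 6 were higher, 2 lower (6 and 3 adjusted over the list alone), at adjusted p = 0.0354, adjusted p = 0.357 with an estimated correlation. The NADPH oxidase rose, with Ncf4 (1.04 ± 0.13) and Cybb (0.50 ± 0.091). Of the 8 measured, 2 were higher, 0 lower (5 and 0 adjusted over the list alone), at adjusted p = 0.0397, adjusted p = 0.262 with an estimated correlation. The inflammasome list rose, with the death receptor Fas (2.01 ± 0.27) higher and the adaptor Pycard (-1.94 ± 0.22) lower. Among 15 measured, 6 were higher, 2 lower (7 and 3 adjusted over the list alone), at adjusted p = 0.0474, adjusted p = 0.497 with an estimated correlation.

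LPS added to IFNg lowered MHC class II presentation, with H2-Ob (-3.74 ± 0.30) and Ciita (-3.13 ± 0.40). Of 11 measured, 0 were higher, 5 lower (0 and 6 adjusted over the list alone), at adjusted p = 0.00171, adjusted p = 0.455 with an estimated correlation. The cell cycle list fell, with Birc5 (-5.08 ± 0.38) and Top2a (-4.09 ± 0.30) behind Rrm2. Of the 27 measured, 0 were higher, 23 lower (0 and 23 adjusted over the list alone), at adjusted p = 8.29e-16, adjusted p = 0.106 with an estimated correlation. The TCA cycle fell, with Suclg2 (-1.83 ± 0.14) and Fh1 (-1.38 ± 0.17). Among 19 measured, 1 was higher, 11 lower (1 and 13 adjusted over the list alone), at adjusted p = 0.00031, adjusted p = 0.492 with an estimated correlation. Oxidative phosphorylation fell, with Uqcrfs1 (-0.77 ± 0.16) and Ndufb5 (-0.63 ± 0.15). Of 26 measured, 0 were higher, 9 lower (1 and 10 adjusted over the list alone), at adjusted p = 0.00166, adjusted p = 0.497 with an estimated correlation. Cholesterol synthesis fell, with Dhcr7 (-2.50 ± 0.42) and Idi1 (-2.12 ± 0.28). Of the 16 measured, 0 were higher, 9 lower (0 and 10 adjusted over the list alone), at adjusted p = 0.000284, adjusted p = 0.42 with an estimated correlation. Ribosomal proteins fell, with Rps18 (-1.23 ± 0.14) and Rps19 (-0.93 ± 0.15). Among 11 measured, 0 were higher, 8 lower (0 and 11 adjusted over the list alone), at adjusted p = 6.07e-06, adjusted p = 0.262 with an estimated correlation. Quantile normalization ended the calls of the NADPH oxidase and the inflammasome (adjusted p = 0.341 and 0.0833), and median centring that of the inflammasome (adjusted p = 0.0747). A replicate block ended that of costimulation (adjusted p = 0.0659). With the arrays numbered 1 left out 6204 genes were called. Of the 4970, 4684 (94.2%) kept call and direction. There the members higher and lower were 5 and 0 of 8 for the NADPH oxidase, 0 and 8 of 11 for MHC class II, 14 and 0 of 18 for chemokines and 1 and 14 of 26 for oxidative phosphorylation.

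IFNg added to LPS raised Ubd (6.05 ± 0.61), a ubiquitin-like protein, Cnn3 (5.39 ± 0.93), an actin-binding protein, and Clic5 (4.46 ± 0.49). It lowered Serpinb2 (-4.43 ± 0.73), the hemoglobin-binding Hp (-4.05 ± 0.60) and U90926 (-3.62 ± 0.52). Nos2 (3.05 ± 0.27) and Cxcl9 (3.02 ± 0.31) were higher as well. In all, 1412 of 18194 genes were called, 621 higher and 791 lower, and 539 of them changed at least 2-fold. After median centring 445.0 were higher and 895.0 lower. GTPases rose, with Gbp8 (4.44 ± 0.29) and Gbp2b (4.40 ± 0.30). Of 10 measured, 9 were higher, 0 lower (10 and 0 adjusted over the list alone), at adjusted p = 5e-14, adjusted p = 0.133 with an estimated correlation. MHC class II presentation rose, with Ciita (2.21 ± 0.40). Of the 11 measured, 4 were higher, 0 lower (6 and 0 adjusted over the list alone), at adjusted p = 0.000125, adjusted p = 0.488 with an estimated correlation. MHC class I presentation rose, with Nlrc5 (1.23 ± 0.18) and Tap2 (1.06 ± 0.13). Among 15 measured, 4 were higher, 0 lower (5 and 0 adjusted over the list alone), at adjusted p = 0.000125, adjusted p = 0.342 with an estimated correlation. Costimulation rose, with Cd40 (2.32 ± 0.43) and Cd86 (2.24 ± 0.33). Of 12 measured, 3 were higher, 1 lower (7 and 2 adjusted over the list alone), at adjusted p = 0.00317, adjusted p = 0.342 with an estimated correlation. Glycolysis rose, with Pfkp (1.56 ± 0.25) and Hk3 (1.08 ± 0.15). Of the 17 measured, 4 were higher, 0 lower (7 and 0 adjusted over the list alone), at adjusted p = 0.000125, adjusted p = 0.488 with an estimated correlation. The inflammasome list rose, with Ripk3 (1.37 ± 0.19), a kinase of necroptosis. Among 15 measured, 3 were higher, 1 lower (5 and 1 adjusted over the list alone), at adjusted p = 0.0484, adjusted p = 0.727 with an estimated correlation. Antioxidant defence rose, with Gsr (0.81 ± 0.21) its 1 called member. Of 19 measured, 1 was higher, 0 lower (3 and 0 adjusted over the list alone), at adjusted p = 0.0297, adjusted p = 0.727 with an estimated correlation. Cell cycle genes fell, with the DNA helicase subunit Mcm6 (-0.85 ± 0.17). Of the 27 measured, 1 was higher, 5 lower (1 and 6 adjusted over the list alone), at adjusted p = 0.00124, adjusted p = 0.727 with an estimated correlation. Ribosomal proteins fell. Among 11 measured, 0 were higher, 4 lower (0 and 6 adjusted over the list alone), at adjusted p = 0.000125, adjusted p = 0.488 with an estimated correlation.

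Without LPS replicate 2, 3 or 4 the count of genes called when IFNg was added to LPS was 907, 884 and 936. It was 936 without IFNg+LPS replicate 2, up to 1963 without IFNg+LPS replicate 1, and 590 when only those groups were fitted. The call of Gsr was lost without LPS replicate 1, 3 or 4 or IFNg+LPS replicate 2, 3 or 4 (0.71 to 0.81, adjusted p up to 0.085), after median centring (adjusted p = 0.0814) and when only those groups were fitted (adjusted p = 0.072). The antioxidant call was lost after quantile normalization (adjusted p = 0.0555), and the inflammasome call without the arrays numbered 1 (adjusted p = 0.09) and after median centring (adjusted p = 0.0513). With the arrays numbered 1 left out 3574 genes were called. Of the 1412, 1365 (96.7%) kept call and direction. Members higher and lower there were 8 and 0 of 11 for MHC class II, 7 and 0 of 15 for MHC class I, 12 and 1 of 17 for glycolysis, 9 and 0 of 19 for antioxidant defence, 7 and 2 of 12 for costimulation, 6 and 2 of 15 for the inflammasome and 0 and 7 of 11 for ribosomal proteins.

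The change with both stimuli was set against the sum of the single changes on the log2 scale. Furthest above the sum were Mmp12 (6.57 ± 1.16), Slc40a1 (5.23 ± 0.63), the iron exporter ferroportin, and Mamdc2 (4.90 ± 0.99). Either stimulus had lowered Slc40a1 and Mamdc2. Mamdc2 had to exceed its sum, which lay below any possible value. Mmp12 fell with IFNg and did not pass with LPS (-1.53 ± 0.82, adjusted p = 0.212) or both (-1.26 ± 0.82, adjusted p = 0.279). Furthest below were Cxcl9 (-7.25 ± 0.43), Cxcl10 (-5.68 ± 0.33) and Gbp6 (-5.61 ± 0.46), which either had raised. With pseudocounts of 1 and 64 Cxcl9 lay at -9.37 and -5.48. Nos2 (3.23 ± 0.38) and the transcription factor Klf4 (3.32 ± 0.44) lay above the sum. In all, 1210 genes departed from it, 550 above and 660 below, 755 of them by at least 2-fold. Every GTPase lay below the sum, with Iigp1 (-5.35 ± 0.43) and Gbp2b (-5.04 ± 0.43) behind Gbp6. Of 10 measured, 0 were higher, 10 lower (0 and 10 adjusted over the list alone), at adjusted p = 9.72e-30. MHC class I presentation lay below it, with Psmb9 (-2.15 ± 0.25) and Psmb8 (-1.85 ± 0.21). Of the 15 measured, 0 were higher, 10 lower (0 and 11 adjusted over the list alone), at adjusted p = 4.17e-16. JAK-STAT genes lay below it, with Socs1 (-2.45 ± 0.38) and Stat2 (-1.67 ± 0.34). Among 15 measured, 1 was higher, 5 lower (1 and 7 adjusted over the list alone), at adjusted p = 4.73e-05. These 3 calls held with an estimated correlation. Antiviral genes lay below it, with Zbp1 (-4.40 ± 0.46) and Ifit2 (-3.68 ± 0.37). Of 23 measured, 0 were higher, 19 lower (0 and 22 adjusted over the list alone), at adjusted p = 1.44e-25, adjusted p = 0.142 with an estimated correlation. Of the 33 measured GTPase and antiviral genes, 27 were with both stimuli within 0.5 log2 of the higher single stimulus, 1 was above that and 5 below. Nrros lay below the sum (-0.61 ± 0.17, adjusted p = 0.0437). That call was lost on leaving out any 1 of 12 arrays (-0.64 to -0.53, adjusted p from 0.0629 to 0.0981). Quantile normalization, median centring, a pseudocount of 1 and every probe set also ended it (adjusted p = 0.0672, 0.0723, 0.0527 and 0.0632).

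Chemokines lay below the sum, with Ccl8 (-4.99 ± 0.68) behind Cxcl9 and Cxcl10. Of the 18 measured, 0 were higher, 5 lower (1 and 6 adjusted over the list alone), at adjusted p = 0.000483, adjusted p = 0.286 with an estimated correlation. MHC class II presentation lay below it, with H2-Ob (-3.60 ± 0.43). Among 11 measured, 0 were higher, 2 lower (0 and 4 adjusted over the list alone), at adjusted p = 0.000165, adjusted p = 0.356 with an estimated correlation. The inflammasome list lay below it, with Mlkl (-2.13 ± 0.30). Of 15 measured, 0 were higher, 4 lower (0 and 4 adjusted over the list alone), at adjusted p = 0.00874, adjusted p = 0.392 with an estimated correlation. The cell cycle list lay below it, with Birc5 (-2.46 ± 0.54) and Aurkb (-2.18 ± 0.32). Of the 27 measured, 1 was higher, 7 lower (1 and 16 adjusted over the list alone), at adjusted p = 1.09e-08, adjusted p = 0.333 with an estimated correlation. Oxidative phosphorylation lay below it, with Ndufs3 (-0.83 ± 0.20). Among 26 measured, 0 were higher, 3 lower (0 and 6 adjusted over the list alone), at adjusted p = 4.5e-06, adjusted p = 0.356 with an estimated correlation. The TCA cycle lay below it, with Sdhb (-0.57 ± 0.12). Of 19 measured, 0 were higher, 4 lower (0 and 4 adjusted over the list alone), at adjusted p = 0.00265, adjusted p = 0.525 with an estimated correlation. Ribosomal proteins lay below it, with Rps18 (-0.90 ± 0.19) the 1 called member, at -0.41 in its next brightest probe set (adjusted p = 0.257). Of the 11 measured, 0 were higher, 1 lower (0 and 3 adjusted over the list alone), at adjusted p = 0.00126, adjusted p = 0.377 with an estimated correlation. Cholesterol synthesis lay above the sum, with Sqle (2.50 ± 0.41) and Hmgcs1 (1.17 ± 0.18). Among 16 measured, 5 were higher, 0 lower (9 and 0 adjusted over the list alone), at adjusted p = 1.75e-05, adjusted p = 0.356 with an estimated correlation. Antioxidant defence lay above it, with Srxn1 (2.96 ± 0.54) and Nqo1 (2.63 ± 0.62). Of 19 measured, 5 were higher, 1 lower (10 and 1 adjusted over the list alone), at adjusted p = 0.00027, adjusted p = 0.356 with an estimated correlation. The lysosome list lay above it, with the lipase Lipa (1.10 ± 0.20) above and Ppt1 (-1.82 ± 0.24) below. Of the 23 measured, 5 were higher, 1 lower (7 and 1 adjusted over the list alone), at adjusted p = 0.00306, adjusted p = 0.392 with an estimated correlation. The next brightest probe set of Cxcl9 lay -1.99 from the sum (adjusted p = 0.123). Median centring moved the share of called genes below the sum from 54.5% to 68.0% and the median over all genes from 0.039 to -0.072. With the arrays numbered 1 left out 3362 genes were called. Of the 1210, 1173 (96.9%) kept call and direction. There the members higher and lower were 0 and 5 of 11 for MHC class II, 1 and 16 of 27 for cell cycle, 11 and 1 of 19 for antioxidant defence, 1 and 7 of 18 for chemokines, 1 and 10 of 26 for oxidative phosphorylation, 9 and 1 of 23 for the lysosome, 2 and 5 of 15 for the inflammasome and 0 and 5 of 11 for ribosomal proteins.

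**Figure D4:**
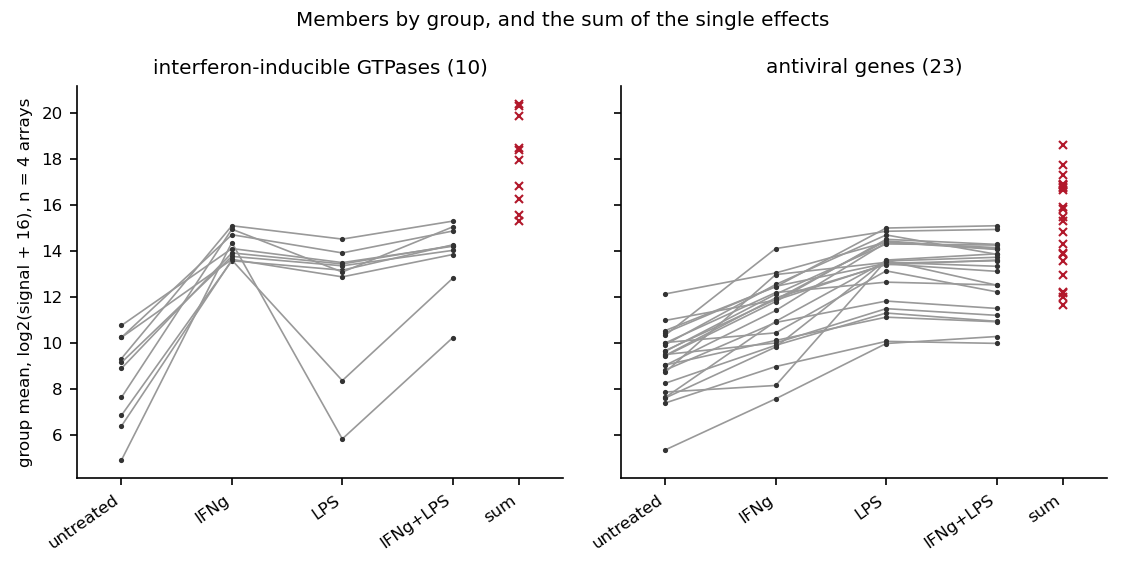
Group means of the 10 measured interferon-inducible GTPases (left) and the 23 antiviral genes (right), as log2(signal + 16) with n = 4 arrays per group, each line 1 gene. Crosses give the level that the sum of the single effects would reach, and the median member lies 2.53 below it with both stimuli.

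**Figure D5:**
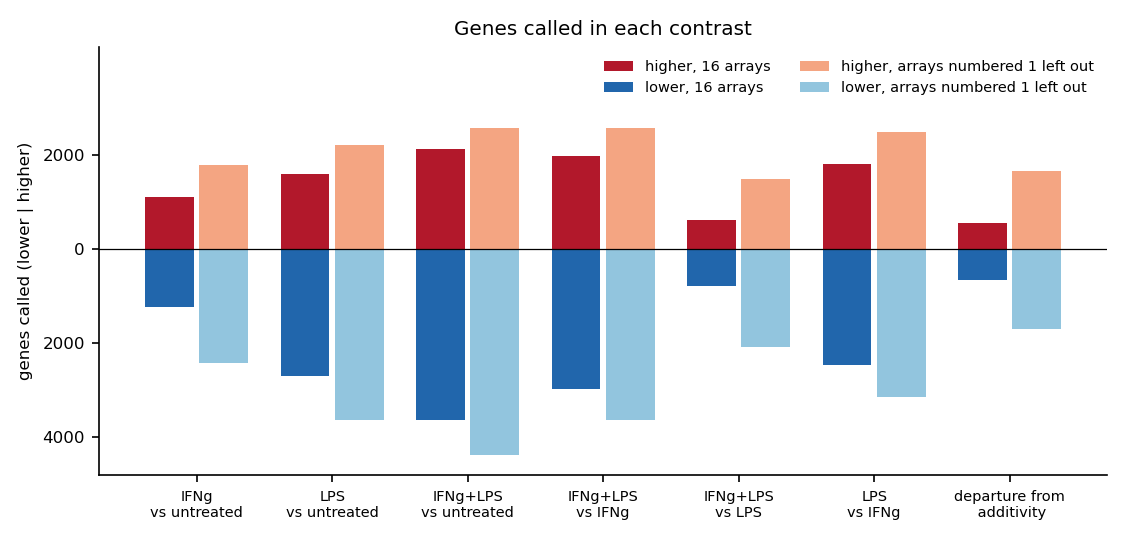
Number of genes called higher (up) and lower (down) in each of the 7 contrasts, with all 16 arrays (dark) and with the arrays numbered 1 left out (light). The counts with all arrays run from 1210 for the departure from additivity to 5761 for both stimuli against untreated cells.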

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

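The tests in this part were chosen after the result was seen, except that of Nrros against genes at its signal level. The normalizations applied to Nrros had been planned as alternatives, and their use against scaling was not. Chance flags about 1 in 20 groups of 4 arrays. Over 225 named genes in 4 groups, 139 of 900 had 1 array apart from the other 3, and in 127 it was the array numbered 1. Values are log2(intensity + 16). In array 1 Nrros stood apart with IFNg at 12.78 and with both at 11.24, Ncf1 with both at 13.45, and Rac2 at 13.62 untreated, 13.23 with IFNg and 14.11 with both. Cybc1 stood apart in LPS array 1 at 11.30 and Rap1a in IFNg array 2 at 13.21. So did Cxcl9 in IFNg array 1 at 13.99, Gbp6 with both in array 1 at 14.79, and in untreated array 1 Mmp12 at 11.26, Mamdc2 at 7.20, Emp1 at 11.74, Fabp4 at 11.24 and Cd28 at 10.02. In LPS array 1 these were Emp1 at 12.38, Il1a at 9.78, Clic5 at 11.26 and Igfbp4 at 6.92, and in array 4 with both Ighm at 6.19. Of 196 other named genes, 34 had an array apart in untreated cells, 17 with IFNg, 28 with LPS and 40 with both.

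The arrays numbered 1 differed from their groups, with 14% of 8167 bright genes lower and 8.07% higher in array 1 in all 4 groups. Degradation of RNA was argued against by Gapdh, whose 3' minus 5' signal was higher in array 1 in 1 of 4 groups. Scaling was argued against by the fibroblast difference, which was -2.17 over the groups and -2.10 after quantile normalization. Fewer fibroblasts or granulocytes in these cultures stay open, since 4 of 6 bright fibroblast markers and 3 of 7 bright granulocyte markers were lower in array 1 than in each other array of its group, in all 4 groups, and macrophages can express some of them. No label sets these arrays apart, and partial activation of untreated array 1 is weighed under the other observations.

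Nrros was lower with LPS and with both. Scaling was argued against, since the smallest fall under the other normalizations was -0.792. A smaller share of macrophages was argued against by the macrophage identity list, whose median with both stimuli was 0.0406 over 15 genes, of which 12 fell less than Nrros. A general fall at its signal level was argued against, since 8.8% of 727 genes within 0.5 log2 of it fell more, with a median of -0.193. Regulation of Nrros mRNA by LPS may remain as a hypothesis, found and tested on the same data.

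The departures from additivity were -0.61 for Nrros, 6.57 for Mmp12, 5.23 for Slc40a1, 4.90 for Mamdc2, -7.25 for Cxcl9, -5.68 for Cxcl10 and -5.61 for Gbp6. Over 33 GTPase and antiviral genes the median was -2.53. Saturation at the top of the array range was argued against as the whole cause. The 10 members whose additive level lay within it, none a GTPase, had a median of -1.52 (bootstrap standard error 0.25). The other 23 with both stimuli lay at a median of -1.18 (standard error 0.12) from the lowest array maximum. It cannot be told apart from a true limit for the 5 members within 0.5 log2 of that maximum, nor can a lower plateau of single probe sets for the 27 within 0.5 log2 of the higher single stimulus. Activation of untreated array 1 was argued against as the whole cause, since the median was -2.73 without the arrays numbered 1. A ceiling in induction that the stimuli share may stay open as a hypothesis for those 27. It does not explain Gbp2b, at 14.36 with IFNg, 5.83 with LPS and 10.23 with both.

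Of 9160 probe sets without a gene here, 172 were called with IFNg, 427 with LPS and 719 with both. For each count of changed genes only 1 of 35 splits of 8 arrays, the real one, gave as many, the smallest share possible. Every other split mixes arrays of the compared groups, which puts the effects of the stimuli into the residuals. Few genes could then be called, so the splits cannot decide on chance. The real counts were 2345 for IFNg, 4281 for LPS and 5761 for both against untreated cells, and the highest of other splits 5, 19 and 81. They were 4970, 1412 and 4283 for both against IFNg, both against LPS and LPS against IFNg, and the highest of others 1, 90 and 2. For the departure, residuals within groups were dealt at random to arrays with additive group means, which avoids this. There 1210 genes stood against at most 4, in 1 real and 99 random deals of 100, which argued against chance for that count.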

How the results depend on the processing

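The alternative without the arrays numbered 1 was chosen after the data were seen, all others before. Of 554 named-gene results 18 reversed, each in the next brightest probe set, and the cause was not tested. These were Cybc1 (-0.27 with IFNg, -0.36 with LPS, -0.35 with both), Rac2 (-0.72 with LPS, -0.80 with both), Rps6 (0.18 and 0.28), and with LPS H2-DMb2 (-0.013), Cx3cr1 (0.027) and Ddit3 (-0.27). For both against IFNg they were Myh10 (0.27), Ebf1 (-0.21) and Gata2 (-0.20), for LPS against IFNg Trem2 (0.13), Ddit3 (-0.091), Bcl2 (0.46) and Ebf1 (-0.31), and for the departure Pfkfb3 (0.053). Another 26 uncalled results changed sign. No list reversed. Of the list calls 84 were lost with an estimated correlation, 10 with quantile normalization, 7 with median centring, 6 without the arrays numbered 1 and 4 each with the mean of probe sets and with a replicate block.

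Counts of called genes moved by over 1.5 times as follows, and the cause was not tested except that every probe set tests 34945 in place of 18194. Array weights gave 4357 for IFNg, 3090 (879 at least 2-fold) for both against LPS, 3132 (1453) for the departure and 2012 for the overlap. Every probe set gave 3711 (1637) for IFNg, 7412 (3320) for LPS, 9986 (4706) for both, 8584 (3797) for both against IFNg, 7296 (3191) for LPS against IFNg, 839 at least 2-fold for both against LPS, 1147 at least 2-fold for the departure and 1618 for the overlap. Only the groups of the contrast gave 590 for both against LPS. A replicate block gave 1888 for the departure. The main fit did not pair arrays by number, since the labels state no pairing. A cut of 0.1 was passed by 13 of 24 same-number pairs, and 14 of 16 arrays were closest to their own number. Without the arrays numbered 1 all 12 arrays were, and the 18 same-number pairs lay at 0.0357 to 0.134 (median 0.0584, against -0.0476 for different numbers). Without the arrays numbered 1 there were 4214 for IFNg, 3574 (939) for both against LPS, 3362 (1494) for the departure and 2064 for the overlap, against 1011. With untreated arrays split the overlap was 524 to 633, and with simulated unchanged groups, where almost no gene was called, 0. Leaving out 1 array gave 884 to 1963 for both against LPS. The fall of Nrros was called in every alternative run, from -0.98 to -0.84 with LPS and -1.56 to -1.46 with both on leaving out 1 array. Signal near background limits fold changes, as for Cxcl9 with IFNg.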

Other observations

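Gene families were grouped by the stem of their symbols after the data were seen, 267 in all. The Schlafen genes rose with LPS, 7 of 7 members with a median of 2.37 (adjusted p = 8.27e-10, adjusted p = 0.2 with an estimated correlation), among them Slfn4 (7.41 ± 0.58). Proteasome subunits rose with LPS, 7 of 7 of the Psma genes (median 0.64, adjusted p = 3.46e-06, adjusted p = 0.126 with an estimated correlation) and 9 of 10 of the Psmb genes, of which 3 were on the fixed lists (median 0.82, adjusted p = 6.05e-07, adjusted p = 0.0439 with an estimated correlation). Psmb7 fell (-0.53 ± 0.13). The Slamf receptors rose with LPS, 4 of 5 (median 2.77, adjusted p = 0.000112, adjusted p = 0.0439 with an estimated correlation).

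Partial activation of untreated array 1 is a hypothesis chosen and tested after the result was seen. Across 9072 genes, which are not independent replicates, the difference of untreated array 1 from other untreated arrays correlated with the LPS effect of the other arrays at 0.388 to 0.461, with a slope of 0.251 to 0.301. Other untreated arrays correlated at -0.519 to 0.152, the highest with array 1 as baseline. IFNg array 1 gave 0.152 to 0.253, so a lesser resemblance was not special to untreated array 1. IFNg array 2 gave 0.257 with baseline array 1, and -0.0733 and -0.0761 with others.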
